A study of Arabidopsis thaliana with 4 samples.

How the data were processed

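Histone H3 chromatin immunoprecipitates and their inputs from seedlings, grown for about 10 days in liquid medium without treatment, were compared on 2-colour arrays, per the labels' protocols. The DNA was amplified and labelled directly with Cy3 and Cy5, per the labels' protocols. Samples were grouped from the labels: the 4 arrays form 1 group, H3, with replicates I and II, called 1 and 2 here, each hybridised with the precipitate in Cy5 and again in Cy3. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

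The deposited values are 1 ratio score per feature and array, in a single table that the authors made from their arrays. The scanner's intensities were not used here. The normalization, the base of the logarithm, the centring, the numerator of the ratio, the genome build and the array design are not given in the sources used here. What the values show is that the columns are not centred on zero (medians 0.23 and 0.13) and that the arrays of each dye swap hold identical values at all 21732 measured features. The authors' values were thus already combined over each dye swap or copied between its arrays, and the dye effect cannot be estimated from them. If the base were 2, a score of 0.5 would be a 1.41-fold ratio and a score of 1 a 2-fold ratio. Of the 21800 listed features, 68 were empty on all 4 arrays, 39 of them with control-like names and 29 with plate and well codes, 13 of these in plate TC25. No value was recorded for a control-like name.

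The arrays of a dye swap were averaged (which changes no value), each replicate was centred on its median, and each feature was tested against zero with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment at 5%. The sides are reported as above or below the array median. The prior degrees of freedom came out as infinite, so all features shared 1 residual SD of 0.157. The observed residual SD varied with the level: it was 0.213 in the 20% of features with the lowest means, 0.108 in the middle 20% and 0.172 in the highest 20%. Part of this is the wider spread of replicate 2. The means of replicates 1 and 2 were -0.28 and -0.52 in the lowest 20%, 0.003 and 0.002 in the middle, and 0.36 and 0.54 in the highest. The test was checked on simulated data with the real number of features and the real pooled spread, of which 200 were changed. It recovered 1% of the features changed by 0.25 units, 86% of those changed by 0.5 and 100% of those changed by 1, and unchanged features made up 3.37% of the calls at 0.5 and 6.10% at 1. With 200 changed features the smallest distance called was 0.39 units at both of these sizes, against 0.26 in the real data, so the simulated recovery does not carry over to the real threshold. The array number limits the precision, and a depth does not apply to these data.

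The test of the features, a first set of alternatives and the rule for named features were fixed before the data were examined. Further alternatives, named below, were added afterwards. The rule takes features that pass the test with the same sign on all arrays, ranked by mean, and at most 2 codes per direction where no gene or position is known. The assumed log2 scale was not borne out by a source, so the values are given in score units and the same test was used. The planned comparisons by annotation class and along the chromosome, and the 7 gene lists, were not run because none of the measured codes matched an entry of the gene table for assembly TAIR10.1 (0 of 21732). The 7 lists held genes of chromosome 4 only. The use of plates as regions, the correlation between successive wells and the comparison with gene order were added after the data had been seen. The plate is the first 4 characters of a feature's code. Plate medians were tested across 231 plates with the same limma functions as the features, and the 6 sets of plates by the difference between their median and that of all other features. For the plates the prior degrees of freedom were 2.21, so each plate's own spread entered its standard error (0.030 to 0.091). Correlations between wells used the 200 plates with all 96 wells measured. They were compared with 1000 shuffles of wells within plates or 10000 random pairings, and intervals are 95% ranges over 1000 resamples of plates. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps and the plots. Alternatives covered the centring, the scaling, quantile normalization, the variance model, the thresholds, the features used and each replicate left out.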

Results

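Chromatin immunoprecipitation with an antibody against histone H3 was compared with its own input DNA in 10 day old Arabidopsis thaliana seedlings of the reference ecotype Col-0. Histone H3 is a core component of the nucleosome, and an antibody directed at H3 itself, rather than at a modified form, is generally used to measure where nucleosomes lie. The series title places the experiment in the mapping of a reference epigenome for seedlings, and the question addressed here is how the H3 signal relative to input is distributed over the features of the array. There was 1 group with 2 replicates, and each replicate was hybridised on 2 arrays with the dyes exchanged, giving 4 arrays. A value was present for 21732 of the 21800 listed features. The arrays of each dye swap carried the same value at all 21732 features, so each replicate contributed 1 value per feature and n = 2 throughout. The number of arrays limits the precision.

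The values are a ratio score read here as the logarithm of the ratio between the precipitated and the input channel. Which of the channels is the numerator was not settled by the labels, and neither was the base of the logarithm. "Above" and "below" therefore refer to the deposited score relative to the array median and carry no direction for H3 itself. Both replicates are positively related, so they run the same way. The features are named by plate and well codes (TA22C05 would be plate TA22, row C, well 5), and a table pairing these codes with genes or positions was not used here.

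The scores of the replicates were positively related across the array and differed in spread. Before centring, replicate 1 had a median of 0.23 and an SD of 0.25 over features, and replicate 2 had a median of 0.13 and an SD of 0.39. Scores lay above zero at 86.5% of features in replicate 1 and at 63.2% in replicate 2. Across the 21732 features the replicates correlated with Pearson's r = 0.84 and Spearman's rho = 0.82. After removal of each plate's median the correlation within plates was r = 0.79, and between the 231 plate medians it was r = 0.93. These coefficients are across features or plates, which are not independent replicates, and they describe these arrays. After centring, 17614 features (81.1%) had the same sign in both replicates. The replicates were over 0.5 score units apart at 530 features (2.44%) and over 1 unit apart at 1 feature.

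**Figure D1:**
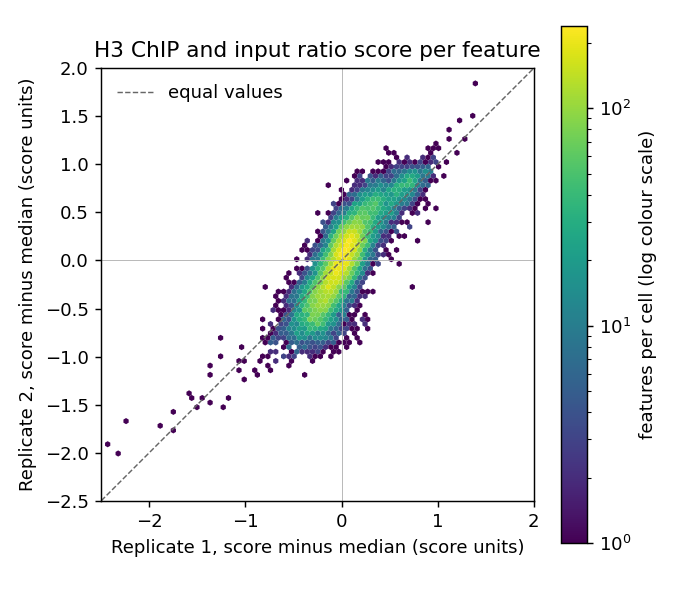
Ratio score of each feature minus the array median, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, both in score units; colour gives the number of features per cell on a log scale and the dashed line marks equal values. The cloud of 21732 features follows a positive relation (r = 0.84) and is wider along the replicate 2 axis (SD 0.39) than along the replicate 1 axis (SD 0.25).

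Both ends of the distribution held features whose distance from the array median was large against the spread between replicates pooled over all features. With limma's moderated test and Benjamini-Hochberg adjustment at 5%, 3697 features (17.0%) were above the median and 4211 (19.4%) were below it. The standard error of a feature's mean was 0.11 score units, and the smallest distance called was 0.26. The same standard error applied to all features, so a feature's own spread between replicates played no part in its call. Some called features had a spread larger than their distance from the median. Of the called features, 7868 (99.5%) had the same sign in both replicates. With a mean at least 0.26 units from the median, opposite signs require replicates over 0.5 units apart. Only 530 features (2.44%) were that far apart, so this agreement in sign follows largely from the selection. At a distance of at least 0.5 units in the mean of the replicates, 1445 features were above and 702 were below. In replicate 1 alone these counts were 1088 and 239, and in replicate 2 alone 2294 and 2191. The balance between the sides depended on the centre. Without centring, 7509 features were above zero and 804 below it. With each array centred on its mode, which lay 0.03 units above the median in replicate 1 and 0.12 units above it in replicate 2, 2525 were above and 5257 below. With the trend and robust options of eBayes together, 2163 were above and 38 below, while the trend option alone gave 4142 and 3694 and the robust option alone 3702 and 4217.

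The highest features that passed were neighbours in plate TA01. TA01A08 had a mean of 1.62 ± 0.32 (SD, n = 2) units above the median and TA01A09 a mean of 1.42 ± 0.10 (SD, n = 2). The lowest were neighbours in plate TA58, where TA58A10 had a mean of -2.17 ± 0.37 (SD, n = 2) and TA58A11 a mean of -2.16 ± 0.22 (SD, n = 2). The limma adjusted p was 1.23e-44 for TA01A08, 3.53e-34 for TA01A09, 1.09e-80 for TA58A10 and 2.80e-80 for TA58A11. These p-values rest on a variance pooled over all features.

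The score differed between plates by more than a random allocation of features would give. Plates were taken as regions after the data had been seen. Differences between plates held 30.8% of the variance of the mean score over features, against at most 1.41% in 1000 shuffles of the features over plates. The shuffles also break the likeness of successive wells described below, so they cannot show that the plate itself is the unit. In 37 of 231 plates the median was at least 0.1 units above the array median in both replicates, and in 18 it was at least 0.1 units below. Of the high plates, 34 fell in 3 runs of successive plate codes, allowing a gap of 1 plate, and the other 3 (TA75, TA95 and TB25) stood alone. The run TA22 to TA28 had a median of 0.14 units in replicate 1 and 0.31 in replicate 2. The run TA35 to TA51 had medians of 0.25 and 0.41. The 13 plates from TC17 to TC30 had medians of 0.42 and 0.58, and each of the 13 was above zero in both replicates. The 3 runs, gaps included, contained 15.1% of the features and 53.9% of the features called above. Within them 60.6% of features were above and 5.48% below, compared with 9.24% above and 21.9% below elsewhere. The runs were chosen on the same values, so that contrast follows in part from the choice. Taken from 1 replicate at a time, 37 of the 39 plates at least 0.1 units above in replicate 1 were so in replicate 2, and 37 of the 53 in replicate 2 were so in replicate 1. Some high plates held few measured features: TA22 and TC17 (60 each), TA38 and TC30 (62 each), TA39 (42), TC25 (64) and TC28 (70). So did PD04 (29) and TC13 (34), whose medians lay below the array median. Whether the score is related to missing wells was not tested.

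**Figure D2:**
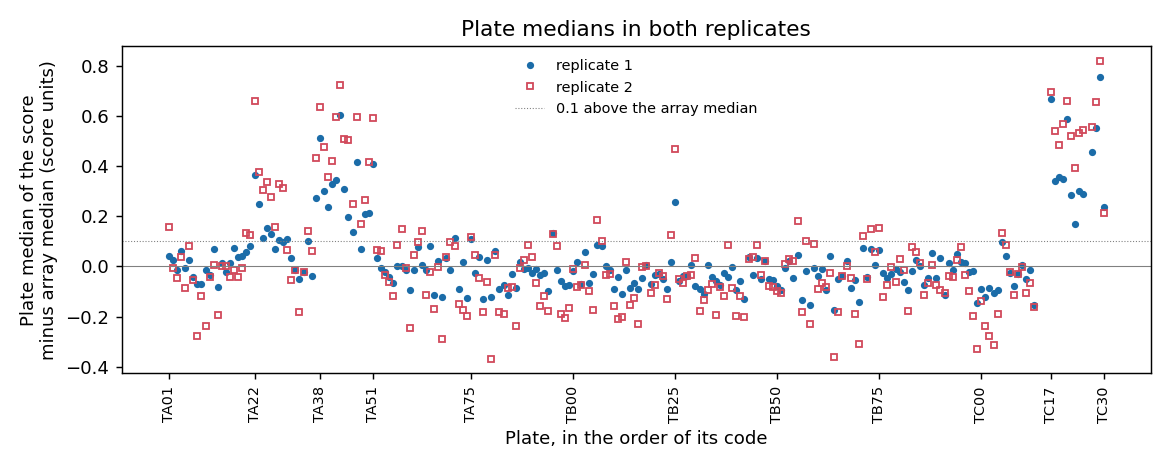
Median score of each plate minus the array median, in score units, for plates TA01 to TC30 in the order of their codes; filled circles are replicate 1, open squares replicate 2, and the dotted line marks 0.1 units. The plates TA22 to TA28, TA35 to TA51 and TC17 to TC30 form the 3 runs of high medians, and TB25 (0.26 and 0.47 units) stands alone.

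The plate with the highest median was TC29, at 0.79 ± 0.04 (SD, n = 2) units, where all 96 features were called above. TC17 followed at 0.68 ± 0.02 (SD, n = 2), with 59 of 60 features above, and TA43 at 0.66 ± 0.08 (SD, n = 2), with 87 of 96 above. The lone plate TB25 had a median of 0.36 ± 0.15 (SD, n = 2), with 58 of 96 features above. The lowest plate median was that of TB64, at -0.27 ± 0.14 (SD, n = 2), with 51 of 96 features below. When the plate medians themselves were tested with limma, 7 plates passed on the high side (TA38, TA43, TC17, TC21, TC27, TC28 and TC29; adjusted p from 0.014 to 0.027) and 0 on the low side. In the same limma fit, 80 plates passed at an unadjusted threshold of 0.05. TB25 (limma adjusted p = 0.091) and TB64 (adjusted p = 0.12) did not pass. A plate's own spread between replicates weighed in this test. TC17 passed with an SD of 0.02, while TA42, at 0.47 ± 0.18 (SD, n = 2), did not (limma adjusted p = 0.078). Scaling both replicates to the same spread before the test raised the count to 53 plates above and 65 below. The 0 on the low side thus does not show that no plate is low.

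The remaining plate sets lay close to the array median or below it. The 100 TB plates had a median of -0.04 ± 0.01 (SD, n = 2) units, with 7.20% of their features above and 21.3% below. The 14 plates from TC00 to TC13 had a median of -0.07 ± 0.04 (SD, n = 2), with 6.01% above and 26.4% below. The 99 TA plates, which include 2 of the 3 runs, had a median of 0.03 ± 0.005 (SD, n = 2), with 22.1% above and 18.3% below. The 4 PD plates had a median of -0.07 ± 0.01 (SD, n = 2), and the single TD plate was at -0.01 ± 0.004 (SD, n = 2). Each set's median was also compared with that of all other features, with limma across the 6 sets. TC17 to TC30 lay 0.52 ± 0.12 (SD, n = 2) units higher (adjusted p = 0.011), TB differed by -0.08 ± 0.02 (SD, n = 2; adjusted p = 0.034) and PD by -0.07 ± 0.01 (SD, n = 2; adjusted p = 0.034). TA (adjusted p = 0.068), TC00 to TC13 (0.061) and TD (0.44) did not pass. After scaling to the same spread, TA (adjusted p = 0.048) and TC00 to TC13 (0.022) passed as well. The 6 comparisons share features, so they are not independent. For TB the rest holds all 3 runs of high plates, so its difference of -0.08, against -0.04 from the array median, in part restates those runs. The split of the TC plates follows a gap in the codes and was made after their values had been seen.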

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

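The centring on the mode, the restriction to plates TA01 to TC13, the trend and robust options taken singly, the scaled count at 0.5 units, the correlations without plates TC17 to TC30, within plates and between plates, and all settings for plates and plate sets were chosen after seeing the data. Scaling to equal median absolute deviations, quantile normalization, the 1% threshold, centring on the mode and the restriction to plates TA01 to TC13 kept the feature counts within 1.5 times of 3697 above and 4211 below. Of those calls, 3675 above and 4151 below were shared with the scaled setting. The restriction gave 2751 above and 4013 below. It kept the centring on all features, so it mainly dropped the calls of the plates left out and says little about robustness. The other 3 settings moved the counts by more. Without centring they were 7509 and 804, as the deposited medians lie above zero. With trend and robust variance together they were 2163 and 38, although either option alone kept them within 1.5 times (4142 and 3694 with trend, 3702 and 4217 with robust), and why they differ only together was not tested. With a minimum size of 0.5 they were 1445 and 702. The plate counts (7 above, 0 below) moved under most settings: to 121 and 0 without centring, 53 and 65 after scaling and 53 and 68 after quantile normalization. They were 27 and 0 with trend and robust variance, 0 and 0 at 1%, and 29 and 62 with centring on the mode. Among full plates, the SD of plate medians was 1.56 times as large in replicate 2. Without scaling, that difference enters the test as spread between replicates. Centring on the mode changes no scale and raised the counts too, so scale is not the only factor. The causes were not tested separately. Of 6 plate sets, 3 differed from the rest in the values as centred and 5 after scaling. The correlation between replicates ranged from 0.79 to 0.93. With 1 replicate left there is no test. The number of features at least 0.5 units above the median (1445) was then 1088 to 2294 and the number below (702) was 239 to 2191, the lower values without replicate 2 and the higher without replicate 1. The number of plates at least 0.1 units above was 39 without replicate 2 and 53 without replicate 1, against 37 in both. Fits on 4 arrays, with a dye term, with the replicate as a random block or within a dye orientation, and the filter on dye-swap differences, were not run, since the arrays of a dye swap hold identical values. The comparisons by annotation class, along the chromosome and for gene lists, with their alternatives, were not run for lack of positions. The smallest distance from the median that passed was 0.26 units.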

Other observations

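The tests on the spread of replicate 2 were chosen after the values had been seen; those on plate boundaries, on rows and on gene order were written down before their results were seen.

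Most features past the threshold had a neighbouring well past it on the same side, although most stretches of successive wells were single features. The 4211 features below the median formed 2105 stretches within plates, 1174 of them single features (median length 1, mean 2.00), and the longest had 14 features, against at most 12 in 100 shuffles of the wells within plates. Of these 4211 features, 72.1% had a neighbour called below as well, against at most 43.8% in the shuffles. Neighbours here are successive measured features of a plate in code order, also across row ends. The 3697 features above formed 1248 stretches, 664 of them single features (median length 1, mean 2.96). The longest was the 96 wells of plate TC29, a full plate that shuffles within plates leave at 96. Of these 3697 features, 82.0% had a neighbour called above, against at most 60.3% in the shuffles. The features farthest from the median were few. There were 19 features at least 1 unit above it, 9 of them in plate TA01 and 7 in the 3 runs of high plates. There were 23 features at least 1 unit below, spread over 18 plates, with 1 in the runs. Low extremes were thus scattered over many plates and high extremes over 6.

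Values of wells that follow each other in the code were alike. Only full plates were used here, which leaves out all plates of the run TA22 to TA28 except TA28. With plate medians removed, successive wells correlated with r = 0.58 in the mean of the replicates, against at most 0.03 in 1000 shuffles (permutation p = 0.001, one-sided, the smallest the shuffles can give). The correlation fell to 0.33 at 2 wells apart, 0.15 at 4 and 0.06 at 8. A well in replicate 1 correlated with the next well in replicate 2 with r = 0.47. Plate handling as the cause would leave the last well of a plate unrelated to the first of the next once plate medians are removed, but they correlated with r = 0.49 over 180 plate pairs, outside the range of -0.14 to 0.15 for random pairs. Adjacency on the plate would leave well 12 of a row unrelated to well 1 of the next, at the opposite edge, but they correlated with r = 0.54, against -0.01 to 0.10 for rows paired at random. Both tests argue against the plate as the source of the likeness of successive wells. As plate medians were removed, they cannot tell whether plate handling contributes to the differences between plates. What remains open, as a hypothesis, is that the codes follow the order of the features in the genome, so that neighbours may share chromatin. The printing order on the slide is not given in the sources used here and stays open as well.

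The high plates come in runs, which would fit large domains if the codes follow the genome. The design gives no group to test this with, so order along a chromosome was tested through the gene table. The medians of the 213 plates from TA01 to TC13 were compared with the share of pseudogene entries in as many bins of equal gene number, for 5 chromosomes in both orientations (10 comparisons). The plates TC17 to TC30, the run with the highest medians, were left out, so these comparisons do not bear on that run. The highest agreement was with chromosome 2 forward, rho = 0.37, and the next with chromosome 4 forward, rho = 0.28. For chromosome 2, 6 of 212 circular shifts gave as large a value of either sign (permutation p = 0.033, two-sided; 0.33 after Benjamini-Hochberg adjustment), and the highest shifted value was 0.44. For chromosome 4 it was 23 of 212 (permutation p = 0.11, two-sided; adjusted 0.42). The values neither single out a chromosome nor exclude one. The planned gene lists held genes of chromosome 4 only, so the plan had presumed that chromosome, which this comparison did not settle. The prediction had counted a missed threshold as evidence against an order, which it is not, and genes per plate need not be equal, so the question stays open.

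Replicate 2 had a wider spread than replicate 1 (SD 0.39 against 0.25), and the labels give no difference between them. Noise independent from feature to feature would lower the correlation at every distance, but with plate medians kept that of successive wells was higher in replicate 2 by 0.059 (95% range over resampled plates 0.033 to 0.091), and with them removed by 0.11 (0.086 to 0.14), which argues against noise as the whole cause. With medians kept the correlation was lower in replicate 2 at 4 wells (a difference of -0.051, -0.082 to -0.014), at 8 (-0.044, -0.078 to -0.0077) and at 32 (-0.053, -0.095 to -0.012), and at 16 the range reached zero (-0.039, -0.077 to 0.00045). At 2 wells the difference was 0.012 (-0.017 to 0.048) with medians kept and 0.059 (0.028 to 0.088) with them removed, higher in replicate 2 as for successive wells. With medians removed the ranges at 4 to 32 wells all included zero. A part from noise stays open. A few outlying features would leave the median absolute deviation alike, but its ratio was 1.91 (1.87 to 1.95). A single scale factor would widen all parts alike: the ratio of SDs was 1.56 between plate medians and 1.60 within plates, but the ratio of interquartile ranges was 1.91 and that of distances from the median to the 99th percentile 1.19, a difference of -0.73 (-0.81 to -0.66). The ratio for the 1st percentile was 1.58, also below that of the interquartile ranges. Both tails thus widened less than the middle, and the upper tail least. A difference in normalization or in hybridisation that is not a simple factor may be involved. No biological explanation was tested.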
